A study of Homo sapiens with 24 samples.

How the data were processed

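Fecal samples labelled as ulcerative colitis (UC, an inflammatory disease of the colon) and samples labelled as healthy were profiled by sequencing part of the bacterial and archaeal 16S rRNA gene, per the labels' protocols. The set held 12 UC and 12 healthy samples. The values used were whole-number counts per taxon and sample, as deposited in 1 table of the whole series with samples as rows and 552 taxon columns, per the file headers. Each column name gave a lineage down to level 7, the species rank. Of the upstream steps, Trim Galore was named in the submitters' processing notes, with no role stated. The classifier, the taxonomy database and the handling of chimeras were not given in the sources used here, and taxon names are printed as in the table, clade suffixes included. Of the row names, 21 matched a sample label exactly and 3 differed from one by 1 more padding zero. Those 3 were taken as healthy samples 1, 2 and 3. With all padding removed, the row taken as healthy sample 3 would share its name with the row of healthy sample 5.

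The group of each sample came from its labels. The labels also carried an extraction kit name, Illumina or Zymo, called the kit label here. The extraction protocol shared by all samples named another manufacturer's kit, so what the kit label records is not settled and it is used only as a batch. Among all samples, 9 of the 12 UC samples carried the Illumina label and 9 of the 12 healthy samples the Zymo label. The healthy samples with the Illumina label were samples 1, 2 and 3, whose rows were matched through padding. Comparisons within that label rest on this match. Nothing in the labels said that the samples of a group came from separate persons, and p-values measure the spread between these samples.

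The 2 columns without a phylum were left out of totals and tests. They held a median of 0.131% of counts in UC samples (highest 4.60%) and a median of 0.0782% in the healthy samples used (highest 0.460%). Healthy sample 7 held 2894 counts, none with a phylum, and was left out of every comparison, which left 11 healthy samples and 23 samples in all. The remaining 550 level-7 taxa were summed to 340 genus labels, of which 300 were named genera and 40 were groups unclassified at that rank, and to 15 phylum labels. Counts with a phylum ranged from 13721 to 99166 per sample. A count of 0 allowed a share of up to 0.0219% in the shallowest and up to 0.00303% in the deepest sample, taking 3 counts as the floor. Amplicon reads carried no molecular identifiers, so floors and 95% Wilson intervals cover counting error only. No 2 samples of a group were duplicates in a chi-square comparison of their counts.

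Genera and level-7 taxa with at least 1 count in at least 6 samples were tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) with TMM factors, the kit label as a covariate and Benjamini-Hochberg adjustment at 0.05. The kit coefficient of the same fit gave the kit comparison, and a fit with the product of group and kit label gave the interaction. Fold changes are UC over healthy on the log2 scale unless stated. Relative abundances are percentages of counts with a phylum, computed from the deposited counts. Phyla with a mean share of at least 0.1%, 10 lists of genera and the log2 ratio of all Bacillota labels to Bacteroidota (Firmicutes to Bacteroidetes) were tested on log2(percent + 0.01). Fold changes on that scale understate changes of rare taxa. The number of level-7 taxa and the Shannon index (natural log) were means of 100 seeded thinnings of each sample to 13721 counts. These values were compared with a two-sided exact permutation test. The statistic was the mean of the UC minus healthy differences within the 2 kit labels, and all 36300 relabellings within kit labels were enumerated, for a smallest possible p of 2.75e-05. Standard errors came from the pooled variance within group and kit label. Bray-Curtis distances of genus shares were analysed by PERMANOVA in vegan 2.7.1 (marginal terms, 9999 permutations within kit label for group and within group for kit label). Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

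The designs, the lists and the alternatives were fixed before the data were examined, except those named as added later. Healthy sample 7 was part of the designs as fixed and was left out once its counts were seen. The rule for named taxa took up to 20 genera past the adjusted threshold by smallest p, the 10 genera with the highest mean share, every label of 23 fixed gut genera whatever its p, up to 10 called level-7 taxa and every phylum tested. It named 42 genus labels. The lists were butyrate producers, other Lachnospiraceae, Ruminococcaceae and Christensenellaceae, Bacteroidales, Enterobacteriaceae and relatives, mouth-associated genera, lactic acid bacteria and Bifidobacterium, mucin specialists, sulfide producers, methanogens, and reagent and skin contaminants. Alternatives were TMMwsp factors, total counts only, DESeq2 1.42.0, limma 3.58.1 on centred log-ratios (0.5 counts added), no detection filter or detection in 12 samples, no kit term, each kit label alone, replicate blocks, other pseudocounts and scales, other distances, and leaving out each sample in turn.

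The tests were tried on counts simulated for the tested genera from their fitted means, library sizes and dispersions, with 20 genera changed per simulation. For UC against healthy over 10 simulations of about 124 genera, edgeR recovered 6.92% of 8-fold changes and 56.1% of 64-fold changes, and 7.89% of its calls at 64-fold were false. At 8-fold, where it made 20 calls in all, 35.0% were false. For level-7 taxa edgeR recovered 1.65% of 8-fold and 52.15% of 64-fold changes. Of its 6 calls at 8-fold 50% were false, and of its 110 calls at 64-fold 11.8%. The simulations raised as many genera or taxa as they lowered, whereas 97 of the 133 genera tested here had a fitted value below 0. The permutation test gave p under 0.05 in 4% of 200 simulations with no shift and in 96% with a shift of 2 SD.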

Results

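The series compared the gut community in feces between 12 samples from ulcerative colitis and 12 samples labelled healthy, by 16S rRNA gene amplicon counts. After healthy sample 7 was left out for having no count with a phylum, 12 UC and 11 healthy samples were compared. Depth followed the kit label more than the group. The 12 samples with the Illumina label held 13721 to 36976 counts (median 19123.5), and the 11 used samples with the Zymo label held 22283 to 99166 (median 62434). The 9 UC and 3 healthy Illumina-labelled samples had median totals of 19080 and 19167, and the 3 UC and 8 healthy Zymo-labelled samples had median totals of 62955 and 59827.5. The main comparisons of the groups, except that of dispersion, were therefore made within kit labels or with the kit label in the model.

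The first question was whether UC samples held fewer kinds of bacteria. At an even depth of 13721 counts, UC samples held 88.7 ± 29.3 level-7 taxa (SD, n = 12) and healthy samples 162.8 ± 28.2 (SD, n = 11). Within kit labels UC samples held fewer taxa, with a difference of -62.8 (SE 12.3, two-sided exact permutation test, p = 0.000165). The difference was -41.8 (SE 16.2, exact permutation p = 0.050) among Illumina-labelled samples, where 3 healthy samples stood against 9 UC samples, and -83.7 (SE 18.8, exact permutation p = 0.0121) among Zymo-labelled samples. The change of the difference between kit labels was not past the threshold in a permutation test (p = 0.280). That test permuted the groups within each label, which assumes no group difference at all. It therefore cannot tell whether the difference was the same under both labels. The lowest counts of taxa were those of UC samples 4 and 12, with 34.9 and 43.1 taxa. The Shannon index, which weighs both the number of taxa and their evenness, was 3.02 ± 0.605 in UC samples (SD, n = 12) and 3.74 ± 0.327 in healthy samples (SD, n = 11). It was also lower in UC within kit labels, by a difference of -0.673 (SE 0.245, exact permutation p = 0.0103). The differences were -0.654 (SE 0.417, exact permutation p = 0.127) under the Illumina label and -0.691 (SE 0.241, exact permutation p = 0.0242) under the Zymo label.

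**Figure D1:**
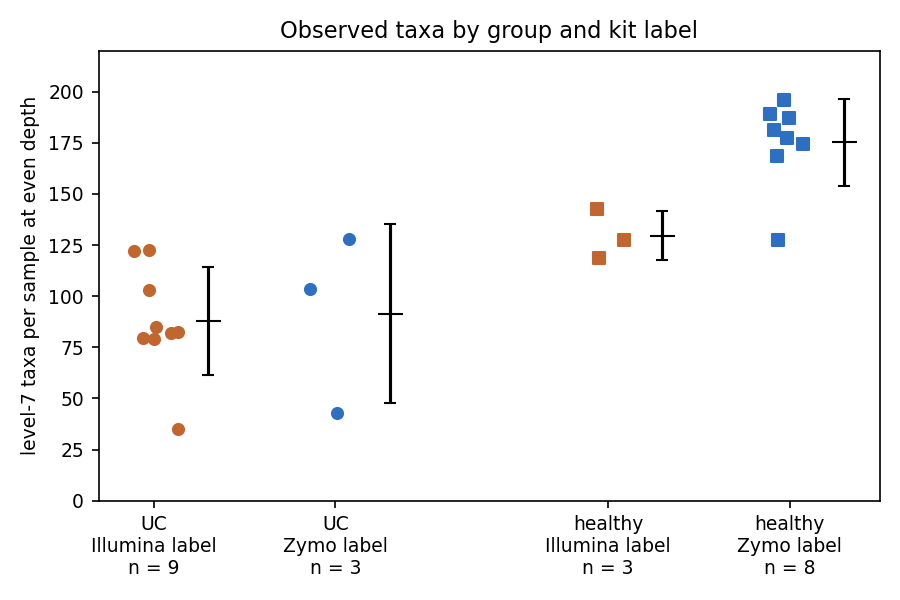
Number of level-7 taxa per sample after thinning to 13721 counts, by group and kit label; each point is a sample (circles UC, squares healthy; orange Illumina label, blue Zymo label), and the bar beside the points gives the mean and SD. UC samples average 87.8 and 91.5 taxa under the Illumina and Zymo labels, and healthy samples 129.6 and 175.2.

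At genus level, 6 of 133 tested genera differed between UC and healthy samples, and all 6 were lower in UC (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). All 6 belonged to Bacillota_A, the phylum label that holds the Clostridia, as did 99 of the 133 tested genera, and no enrichment was tested. Avispirillum was found in 0 of 12 UC and 9 of 11 healthy samples, with a healthy mean share of 0.0550% ± 0.102 (SD, n = 11) and median of 0.0267% (edgeR adjusted p = 0.00513). Butyrivibrio_A_180067, a label of the butyrate-forming Lachnospiraceae, was found in 1 UC and 5 healthy samples and averaged 0.00262% against 0.644% (log2 fold change -8.39, SE 2.33, edgeR adjusted p = 0.0307). PeH17 was found in 1 UC and 9 healthy samples (log2 fold change -6.63, SE 1.67, edgeR adjusted p = 0.0235). Genera unclassified within the Anaerovoracaceae were found in 1 UC and 9 healthy samples (edgeR adjusted p = 0.0235). Genera unclassified within the Christensenellaceae were found in 0 UC and 7 healthy samples (edgeR adjusted p = 0.0307). Their healthy mean share of 0.00986% lay under the share that a count of 0 allows in most Illumina-labelled UC samples. UBA644 was found in 1 UC and 5 healthy samples (edgeR adjusted p = 0.0366). These detections are pooled over kit labels, which differ in depth and in their share of each group. Of the 3 Illumina-labelled and 8 Zymo-labelled healthy samples, Avispirillum was found in 2 and 7, PeH17 in 3 and 6 and UBA644 in 2 and 3. Butyrivibrio_A_180067 was found in 1 and 4, the unclassified Anaerovoracaceae in 1 and 8 and the unclassified Christensenellaceae in 1 and 6. Of the 133 genera, 97 had a fitted value below 0, and the median log2 fold change was -0.84. Under the Illumina label alone the median was -0.21, with 70 of 125 below 0, and under the Zymo label alone it was -2.03, with 107 of 133 below 0. With TMMwsp factors, total counts only and DESeq2, 92, 98 and 86 genera were below 0. Centred log-ratios, which centre each sample by construction, gave a median of 0.15 and 61 below 0. The call was not stable to samples: without UC samples 4 and 12, an alternative added after seeing the data, 1 genus was called, Avispirillum. Leaving out each sample in turn gave 1 to 14 genera; UC samples 1, 2, 3, 5, 6, 10 and 12 and healthy samples 2, 3 and 6 each moved the count by over 1.5 times. Among Illumina-labelled samples alone edgeR called 0 genera, with 9 at an unadjusted p under 0.05, and among Zymo-labelled samples alone it called 10, with 0 of the 6 among them. The fitted log2 fold changes of the 6 stayed below 0 under each label alone, at -7.58 to -3.60 under the Illumina and -11.71 to -2.51 under the Zymo label. The 6 were chosen from these same samples, so their signs are no separate support. For those found in 0 UC samples the sign could not be otherwise. Limma on centred log-ratios called 2 genera, also with 0 of the 6.

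Level-7 taxa gave 12 calls among 182 tested, 11 lower and 1 higher in UC (edgeR). The 5 with the smallest p were found in 0 UC samples: Avispirillum sp011957885, an unnamed taxon of the Ruminococcaceae, an unnamed Lentihominibacter and Butyribacter sp003529475, each in 8 healthy samples, and Bacteroides_H_857956 eggerthii in 6. Detections of taxa are likewise pooled over kit labels, which differ in depth. The Ruminococcaceae taxon averaged 0.149% ± 0.200 in healthy samples (SD, n = 11). Among the other lower taxa were unnamed taxa of the Anaerovoracaceae and Acutalibacteraceae, Butyrivibrio_A_180067 crossotus and PeH17 sp900542285, each in 1 UC sample. The taxon that rose was the part of Enterocloster not resolved to species, which was found in 5 UC and 1 healthy samples and averaged 0.0356% against 0.000956% (log2 fold change 5.46, SE 1.59, edgeR adjusted p = 0.0357). Without UC samples 4 and 12, 5 taxa were called. Among Illumina-labelled samples alone edgeR called 0 taxa, with 13 at an unadjusted p under 0.05, and among Zymo-labelled samples alone it called 1, the unresolved part of Gemmiger_A_73129, which was not among the 12 and was named after its value was seen. The fitted log2 fold changes of the 12 kept their sign under each label alone, with 5.08 and 5.36 for Enterocloster under the Illumina and Zymo labels. The 12 were chosen from these same samples, so their signs are no separate support. For the 5 found in 0 UC samples the sign could not be otherwise.

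The abundant genera did not pass the test. Faecalibacterium, a butyrate producer of the healthy colon, averaged 17.8% ± 12.0 in UC (SD, n = 12) and 13.6% ± 7.27 in healthy samples (SD, n = 11), with a log2 fold change of 0.45 (SE 0.85, edgeR adjusted p = 0.915). Blautia_A_141781 averaged 14.3% ± 7.65 and 13.3% ± 6.57 in the same groups (edgeR adjusted p = 0.590). Prevotella averaged 13.6% ± 21.2 and 10.0% ± 13.6, while its fitted log2 fold change with the kit label in the model was -2.21 (SE 2.81, edgeR adjusted p = 0.848). Bacteroides_H_857956 averaged 6.45% ± 13.4 and 1.38% ± 1.56 (edgeR adjusted p = 0.863). The other genera among the 10 with the highest mean share were Phocaeicola_A, Agathobacter_164117, Gemmiger_A_73129, Ruminococcus_E, Bifidobacterium_388775 and unclassified Lachnospiraceae, and none passed. Ruminococcus_E was found in 5 of 12 UC and 10 of 11 healthy samples, at 1.45% ± 3.12 and 3.74% ± 3.15 (edgeR adjusted p = 0.855). Akkermansia, which feeds on mucin, was found in 2 UC and 5 healthy samples (edgeR adjusted p = 0.944). Escherichia was found in 2 UC and 0 healthy samples and was too rare to test. Of the 33 labels of fixed genera that were detected, 22 could be tested and 0 passed. The smallest p among them was that of Desulfovibrio_446353, found in 2 UC and 5 healthy samples (log2 fold change -4.92, SE 2.26, edgeR p = 0.0375, adjusted p = 0.249).

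Among the lists of genera, 0 of 10 differed between UC and healthy samples after adjustment in the exact permutation test of their summed shares, and 1 had an unadjusted p under 0.05, the sulfide producers. Butyrate producers made up 28.5% ± 14.6 of counts in UC (SD, n = 12) and 28.5% ± 5.77 in healthy samples (SD, n = 11), with an adjusted permutation p of 0.841. Of their 18 tested members 1 fell, Butyrivibrio_A_180067, and 17 did not pass; adjusted over the list alone, 1 passed. The list of other Lachnospiraceae, Ruminococcaceae and Christensenellaceae took 22.2% ± 10.0 and 23.9% ± 8.39, with a within-kit log2 difference of the other sign (0.15, adjusted permutation p = 0.841), and 0 of its 11 tested members passed over all genera or adjusted over the list alone. It went by genus name and so held Ruminococcus_E and Monoglobus, whose lineages give the Acutalibacteraceae and Monoglobaceae. Its share is thus not that of the 3 families. On centred log-ratios 2 lists were past the threshold, these 2, and both were higher in UC. The Bacteroidales list took 26.0% ± 20.7 and 14.7% ± 12.8, with a within-kit log2 difference of -1.15 (adjusted permutation p = 0.346) and 0 of 10 members passing by either adjustment. It went by genus name, so it left out unclassified Bacteroidales and took in Bacteroides_F, whose lineage is Lachnospiraceae. The list took 33.9% in UC against 29.7% in healthy samples under the Illumina label and 2.45% against 9.06% under the Zymo label. The direction of the pooled means was thus not kept under the Zymo label.

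Sulfide producers, bacteria that release hydrogen sulfide, averaged 0.0537% ± 0.106 in UC (SD, n = 12) and 0.158% ± 0.182 in healthy samples (SD, n = 11). Their log2 difference was -2.34 (SE 0.81, exact permutation p = 0.0107, adjusted p = 0.107), and they were found in 6 UC and 10 healthy samples. It was -3.63 (exact permutation p = 0.00909) under the Illumina label, which held 3 healthy samples, and -1.04 (exact permutation p = 0.339) under the Zymo label. The change between kit labels was not past the threshold in a permutation test (p = 0.183), which again cannot tell whether the 2 differences were the same. Neither of their 2 tested members passed, over all genera or adjusted over the list alone. Methanogens, archaea that form methane from hydrogen, were found in 0 of 12 UC and 5 of 11 healthy samples (exact permutation p = 0.0727, adjusted p = 0.346). Enterobacteriaceae and relatives were found in 3 UC and 0 healthy samples (adjusted permutation p = 0.686). Mouth-associated genera averaged 0.157% in UC and 0.380% in healthy samples, but their within-kit log2 difference was 0.92 (adjusted permutation p = 0.686), and their 1 tested member, Streptococcus, did not pass. Lactic acid bacteria and Bifidobacterium averaged 1.98% and 3.20%, but their within-kit log2 difference was 0.34 (adjusted permutation p = 0.931), with 0 of 3 members passing. Mucin specialists averaged 1.03% and 0.587% (adjusted permutation p = 0.931), with 0 of 2 member genera passing. Of these, Mediterraneibacter_A_155507 was tested as a whole genus, although the list took in only 1 of its level-7 taxa. Reagent and skin contaminants were found in 1 UC and 1 healthy sample.

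Among phyla, 0 of 9 differed after adjustment in the exact permutation test within kit labels, and 1 had an unadjusted p under 0.05. On centred log-ratios 1 passed, Bacillota_A_368345, higher in UC. The centre there was the mean over all phylum labels, so undetected phyla lower it and raise an abundant phylum. The smallest p on the log2 scale was that of Desulfobacterota_G_459543, whose counts were those of the sulfide producers (exact permutation p = 0.0107, adjusted p = 0.0964). Bacillota_A_368345 averaged 67.9% ± 18.7 in UC (SD, n = 12) and 74.8% ± 11.4 in healthy samples (SD, n = 11), and Bacteroidota 26.6% ± 20.8 and 15.5% ± 13.1. Actinomycetota averaged 2.11% and 4.95%, Bacillota_I 1.59% and 2.38%, Bacillota_C 0.368% and 0.950%, Pseudomonadota 0.721% and 0.397%, and Verrucomicrobiota 0.354% and 0.495%. These pooled means carry the unequal kit labels of the groups. The within-kit log2 differences had the other sign for Bacteroidota (-1.20), Actinomycetota (0.20), Bacillota_I (0.08) and Bacillota_A_368345 (0.01), none past the threshold. Fusobacteriota was found in 1 UC and 0 healthy samples. The Firmicutes to Bacteroidetes log2 ratio was 2.27 ± 2.80 in UC (SD, n = 12) and 2.88 ± 1.62 in healthy samples (SD, n = 11). Within kit labels its difference had the other sign, 1.22 (SE 0.69, exact permutation p = 0.124), with -0.15 (SE 0.74) under the Illumina label and 2.58 (SE 1.20) under the Zymo label.

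**Figure D2:**
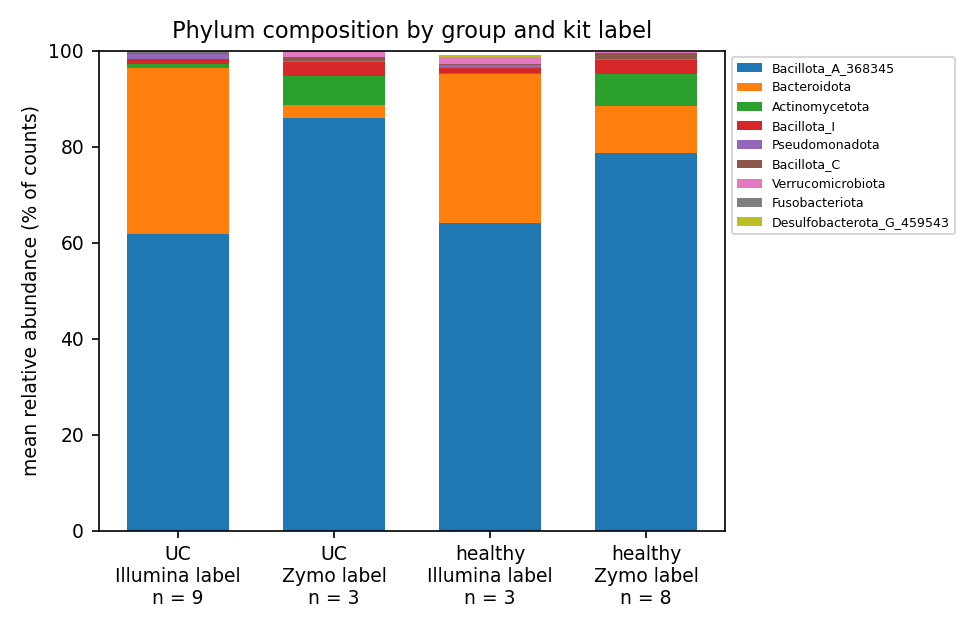
Mean relative abundance (% of counts with a phylum) of the 9 phyla tested, stacked by group and kit label. Bacteroidota takes 34.5% and 30.9% of counts in UC and healthy samples with the Illumina label, and 2.60% and 9.66% in those with the Zymo label.

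In the community as a whole, the kit label took a larger share of the variation in genus shares than the group did. In the PERMANOVA of Bray-Curtis distances, group took 7.16% of the variance (p = 0.0516) and kit label 13.4% (p = 0.0009). On presence of genera at even depth, by Jaccard distance, that order was not kept: group took 10.8% (p = 0.0002) and kit label 10.7% (p = 0.0001, the smallest the permutations can give). By Aitchison distance group took 9.39% and kit label 9.71%. In PERMANOVA of Bray-Curtis distances within 1 kit label, group did not pass under the Illumina (7.90%, p = 0.554) or the Zymo label (15.8%, p = 0.0685). Around 1 centroid per group, with kit labels not separated, UC samples lay farther out than healthy samples did, at 0.411 ± 0.118 (SD, n = 12) against 0.318 ± 0.0498 (SD, n = 11) in a permutation test of dispersion (p = 0.0227), and a difference in spread can itself move a PERMANOVA p. The spread within kit labels was not tested.

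**Figure D3:**
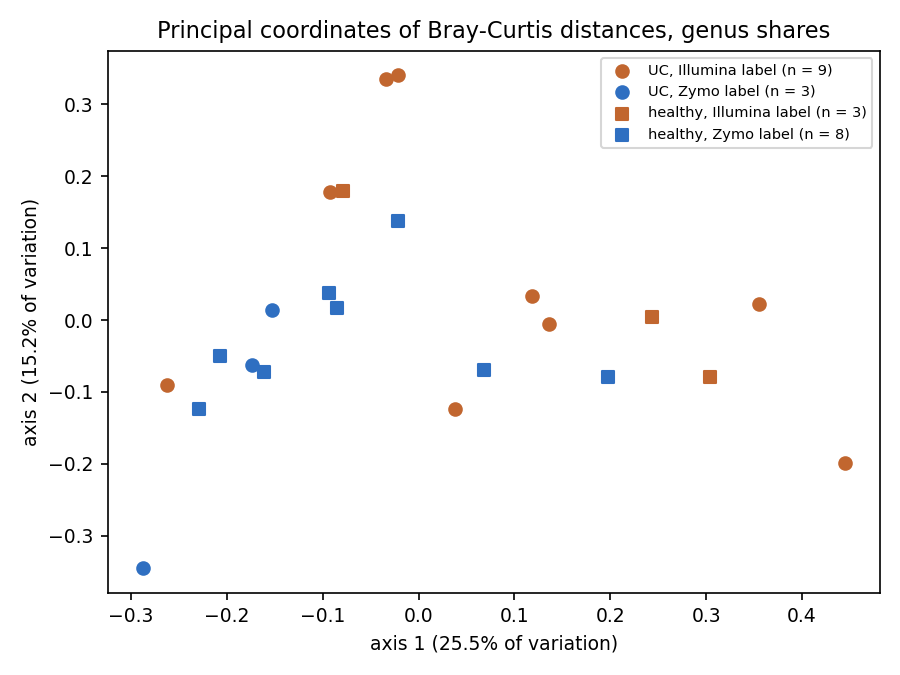
Principal coordinates of Bray-Curtis distances between samples (genus shares); the axes carry 25.5% and 15.2% of the variation, circles are UC and squares healthy samples, orange is the Illumina and blue the Zymo label. Samples of both groups overlap, and the UC samples are the more scattered.

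The kit comparison asked how large the batch difference was. Of 133 genera, 8 differed between kit labels with group in the model, 7 higher and 1 lower under the Zymo label (edgeR adjusted p under 0.05). Streptococcus was higher under the Zymo label, found in 10 of 11 samples there and in 2 of 12 under the Illumina label (log2 fold change Zymo over Illumina 8.14, SE 1.64, edgeR adjusted p = 0.00182). Onthenecus (7.59, edgeR adjusted p = 0.00107), Faecalibacillus, Lawsonibacter, Pauljensenia, Holdemania and Clostridium_A_51961 were also higher, and genera unclassified within Clostridia_258483 were lower (-5.97, edgeR adjusted p = 0.0214). Apart from Streptococcus, the genera of this comparison were chosen for naming after their values were seen. With counts thinned to even depth, 5 genera were called in 1 draw and 5 to 11 over 20 other draws. The interaction of group and kit label gave 0 genera in edgeR, with 23 at an unadjusted p under 0.05, 18 in DESeq2 and 0 in limma on centred log-ratios.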

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

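The tests of the depth of the UC libraries, of the kit label, of cell lysis, of sample splits and of repeated draws at even depth were chosen after the results they bear on were seen. The tests without each sample's 10 most abundant genera and of kit fold changes in a single draw at even depth were written down before their results were seen.

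Counts without a phylum, which were left out of the main totals, lay above the highest value of the other healthy samples (0.460%) in 5 samples. They made up 100% of healthy sample 7 (Wilson interval 99.9% to 100%), 4.60% of UC sample 4 (4.31% to 4.90%), 2.38% of UC sample 9 (2.15% to 2.64%), 1.27% of UC sample 1 (1.16% to 1.39%) and 0.566% of UC sample 6 (0.472% to 0.677%), with Wilson intervals.

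The lower number of taxa in UC samples was weighed against 3 technical explanations. Lower depth of the UC libraries is argued against by the difference at even depth, -62.8 (SE 12.3). A few genera taking most of the counts is argued against because, without each sample's 10 most abundant genera and with the rest thinned to 1502 counts, UC samples still held 62.2 ± 24.8 taxa (SD, n = 12) and healthy samples 118.1 ± 18.5 (SD, n = 11), a difference of -46.8 (SE 9.73, exact permutation p = 0.00011). The kit label as the whole cause is argued against by the smaller of the 2 differences within kit labels, -41.8 (SE 16.2, exact permutation p = 0.050), which lies more than 2 SE below 0 but not under p = 0.05. The disease itself, and treatment, diet or sample handling that went with it, stay open and were not tested.

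The difference between kit labels was weighed against depth and cell lysis. Of the 7 genera higher under the Zymo label, 4 could be tested in a single draw at even depth, and for these depth as the whole cause is argued against by their median log2 fold change of 7.00 (median SE 1.46). The other 3 fell under the detection minimum of 6 samples in that draw. Over 20 draws without this minimum, the lowest of their median log2 fold changes was 3.38 for Holdemania (median SE 0.91, and 4.83 before thinning). Holdemania and Pauljensenia were found in 0 Illumina-labelled samples, so the sign of their fold changes could not be otherwise. They reached 6 samples in only 4 and 9 of the 20 draws. The draws are therefore not used to decide on depth for these 3 genera. Harsher lysis of Gram-positive cells would go with the lower Bacteroidota under the Zymo label (log2 difference -3.32, SE 0.59, exact permutation p = 5.51e-05) and the higher Actinomycetota (4.80, SE 1.11, exact permutation p = 0.000303). As the whole cause, however, it is argued against by Bacillota_C, a phylum label of Gram-negative bacteria, which was higher (3.52, SE 1.16, exact permutation p = 0.00551). This rests mostly on the healthy samples (4.35, SE 1.38, exact permutation p = 0.0242), of which 3 carried the Illumina label. Among UC samples the difference was 2.70 (SE 1.84, exact permutation p = 0.195). Other persons or other handling under the 2 labels stay open.

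Chance as the source of the genus and taxon counts was examined with 100 splits of the samples within strata, the real one included. For UC against healthy, 2 of 100 splits gave at least the 6 genera called, and the highest other split also gave 6. So few drawn splits cannot tell that share from 0.05, so chance was not excluded for the genera. For level-7 taxa only the real split gave 12 calls, and the highest other gave 3. For kit labels only the real split gave 8 genera, and the highest other gave 3. Chance as the whole source is argued against for both of these counts, within the 100 splits drawn. The interaction gave 0 genera (5 in the highest other split), a count that all 100 splits reach whatever the data, so this comparison decides nothing.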

How the results depend on the processing

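Alternatives added after seeing the data were robust dispersion, thinning the counts for the genus, taxon and kit fits, leaving out UC samples 4 and 12, and keeping counts without a phylum in the totals. The cause of a change was not tested unless stated. The fewer taxa and lower Shannon index in UC kept their direction and stayed under p = 0.05 in every alternative except the Illumina label alone, where the differences were -41.8 and -0.654 and fewer samples were used. Leaving out each sample in turn gave -71.9 to -50.7 taxa and -0.766 to -0.529 for the Shannon index.

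The count of 6 genera was 16 with DESeq2 (4 of the 6 among them), 2 with limma on centred log-ratios (SFMI01 and Onthomonas, 0 shared), 31 without the detection filter (9 higher, 22 lower; 3 of the 6), 0 with detection in 12 samples (4 at an unadjusted p under 0.05; none of the 6 was found in 12 samples), 15 without the kit term (all 6), 0 with the Illumina and 10 with the Zymo label alone (0 shared), and 1 without UC samples 4 and 12. Leaving out each sample gave 1 to 14 genera: 1 without UC sample 1, 2, 5, 10 or 12 or healthy sample 3, 2 without healthy sample 6, 10 without UC sample 3 or healthy sample 2, and 14 without UC sample 6. Avispirillum was called in all 23 of these fits and PeH17 in 17. The unclassified Anaerovoracaceae and Christensenellaceae were called in 16 each, and Butyrivibrio_A_180067 and UBA644 in 12 each. The 12 level-7 taxa became 21 with DESeq2 (6 shared), 6 with limma (2 shared), 56 without the filter (6 shared), 0 with detection in 12 samples, 0 and 1 with the Illumina and Zymo labels alone (0 shared), and 5 without UC samples 4 and 12. The 8 genera between kit labels became 18 with DESeq2 (5 shared), 41 without the filter (7 shared), 3 with detection in 12 samples (2 shared) and 5 in 1 draw at even depth (5 shared; 5 to 11 called over 20 other draws). The interaction count of 0 became 18 with DESeq2 and 1 without the filter.

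The Firmicutes to Bacteroidetes log2 ratio changed sign, never past the threshold, to -0.62 without kit strata and -0.15 under the Illumina label. Phyla past the threshold rose from 0 to 1 at a pseudocount of 0.1 percent and without a log (both Desulfobacterota_G_459543) and to 1 on centred log-ratios (Bacillota_A_368345, higher in UC). Lists rose from 0 to 1 without a log (sulfide producers) and to 2 on centred log-ratios, where butyrate producers reversed to 0.91. The centred scale raises an abundant list where fewer genera are detected, as in UC samples. The group's share of variance passed by Aitchison (9.39%) and Jaccard distance (10.8%), at level 7 (7.01%) and in no other alternative. Of the other values, for named genera and taxa, phyla and lists, 505 kept their sign and their side of the threshold, though their size could change. Another 89 fell short of the threshold, 6 came past it and 83 changed sign without passing it or lay at 0. All 89 that fell short were values of called genera and taxa, while the 505 include values of genera, phyla and lists never called.

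Replicate numbers were shared between the groups but gave no sign of pairing. Of 11 same-numbered pairs, 1 correlated above 0.1 (range -0.15 to 0.11). In 2 pairs the healthy sample that correlated best with the UC sample was that of its own number. With the replicate number as a block, edgeR called 1 genus, Prevotella, and 0 level-7 taxa (23 at an unadjusted p under 0.05) and the Firmicutes to Bacteroidetes difference was -0.31; the differences in taxa (-73.4) and Shannon index (-0.607) stayed past the threshold.

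Depth limits rare taxa: under 0.0219% of counts a taxon can be missed in the shallowest sample.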

Other observations

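The counts of taxa per order and family, the share of the top genera and the detection of genera at even depth were examined after the lower number of taxa in UC was seen, and all tests in this part were chosen then.

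Taxa were fewer in UC in several orders of Clostridia and in the Bacteroidales, which also held most of the taxa of healthy samples, and no difference between orders was tested. At even depth, Christensenellales, an order of gut Clostridia, counted 0.703 ± 1.17 taxa per UC sample (SD, n = 12) and 6.74 ± 2.61 per healthy sample (SD, n = 11), a difference within kit labels of -5.44 (SE 0.937, exact permutation p = 5.51e-05, adjusted p = 0.000413). It was lower under the Illumina label (-4.76, exact permutation p = 0.00909) and under the Zymo label (-6.12, exact permutation p = 0.00606). Oscillospirales, which hold Faecalibacterium and the Ruminococcaceae, counted 19.1 ± 10.2 (SD, n = 12) and 41.4 ± 7.42 taxa (SD, n = 11). They were lower within kit labels (adjusted exact permutation p = 0.000413), by a difference of -14.6 under the Illumina and -25.4 under the Zymo label. Lachnospirales (-14.7), Bacteroidales (-10.4), Coriobacteriales (-2.58) and Peptostreptococcales (-1.95) were lower too (adjusted exact permutation p = 0.00358 to 0.0156), but none of these was under p = 0.05 within the Illumina label alone. Under that label Coriobacteriales ran the other way, at 0.889 taxa in UC and 0.647 in healthy samples. Lactobacillales, Burkholderiales, Erysipelotrichales and Veillonellales did not pass, with adjusted exact permutation p between 0.203 and 0.883. The share of Faecalibacterium did not fall with the taxa of its order, at 18.8% and 14.7% in UC and 11.9% and 14.3% in healthy samples under the Illumina and Zymo labels.

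The 10 most abundant genera of each sample took 81.3% ± 8.10 of UC counts (SD, n = 12) and 65.6% ± 7.06 of healthy counts (SD, n = 11), a difference within kit labels of 16.3 (SE 3.79, exact permutation p = 0.000413). Both taxa at or above 0.1% of a sample (-35.7, SE 6.69) and rarer ones (-27.1, SE 6.87) were fewer in UC (exact permutation p = 5.51e-05 and 0.00223). Pielou evenness was not past the threshold (0.681 ± 0.105 and 0.736 ± 0.0520, exact permutation p = 0.180).

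Detection alone gave 3 of 133 genera past the adjusted threshold in the exact permutation test at even depth. It uses no scaling factors, but it still depends on how much of the even depth other genera take. SFMI01 was found in 1 of 12 UC and 10 of 11 healthy samples, Eubacterium_J in 4 and 11, and PeH17 in 1 and 9 (adjusted p = 0.0489 each). At an unadjusted p under 0.05 there were 29 genera, and all 29 were found less often in UC. UC samples also held fewer genera at this depth, so that shared direction is no separate support. Methanobrevibacter_A was found in 0 UC and 4 healthy samples and Methanosphaera in 0 UC and 1 healthy sample.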
